A study of Nicotiana benthamiana with 12 samples.

How the data were processed

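Small RNA was sequenced from leaves of Nicotiana benthamiana, a tobacco relative used for transient expression by Agrobacterium infiltration. Plants had received bacteria carrying NlCSP1 or, as control, green fluorescent protein (GFP), each behind the 35S promoter. The infiltrated leaves and the upper leaves that had not been infiltrated were sampled, which gave 4 groups of 3 libraries, 12 in all. Per the labels' protocols, RNA of 18 to 30 nt was cut from a gel and the primers carried unique molecular identifiers (UMIs).

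The deposited values are whole-number counts of reads per small RNA in each library, beside a deposited number of UMIs. Per the file headers, each entry is a known miRNA, a predicted miRNA, an siRNA or another RNA class such as rRNA, intron, exon or intergenic sequence. The aligner, the prediction tools, the miRNA database release and the rule for reads that fit several near-identical miRNAs are not given in the sources used here. A library lists siRNAs and predicted miRNAs from 10 reads upward and known miRNAs from 1 read upward, so an unlisted siRNA may have held up to 9 reads. Precursors of predicted miRNAs are placed on Niben101 scaffolds as the authors gave them. End minus start equals the precursor length for all 118 of them, so the positions cannot be 1-based with both ends included, and no reference genome was used here.

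The read count was chosen as the measurement before any test was run. Among siRNA values, UMIs were a median 100% of reads for values of 10 to 100 reads and 44.7% for the 2 values above 100000 reads, and the UMI number was therefore an alternative. Known miRNAs, predicted miRNAs and siRNAs made up the library size. The other classes stayed out of library sizes and of the tests of small RNA counts. Rows of bacterial RNA among them were compared separately. Intergenic sequence alone took 77.93% to 81.84% of all reads. Total reads ran from 14801770 to 24862299 per library, and small RNA reads from 671997 to 1544934, or 4.388% to 9.107% of the total. The infiltrated leaves had fewer total reads than the upper leaves, so depth and leaf position coincide.

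Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group, and 1 fit over all 12 libraries with 8 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, two-sided. Standard errors (SE) of log2 fold changes are the absolute value divided by the square root of the F statistic of that test. A difference counted in standard errors therefore restates the test. The filter left 3631 small RNAs, of which 167 were known miRNAs, 58 predicted miRNAs and 3406 siRNAs. Counts of known miRNAs that share a family number were also summed into 52 families, because near-identical members share reads and a single member is uncertain. Some families held only 1 member, among them miR479, miR3627, miR6019, miR6020, miR6021, miR6024, miR4995 and miR5368. For these the family test used the same counts as the single small RNA under another fit, and is no independent evidence. CPM values relate counts to the small RNA reads of a library after TMM scaling. For sums over siRNAs found in some groups alone no TMM factor was used. RPM values of bacterial RNA relate reads to all reads of a library. Family lists for phase change, auxin signalling, leaf and organ development, copper and oxidative stress, phosphate, sulfate and nitrogen, silencing machinery, NLR defence genes, and MYB and phenylpropanoid were fixed before the data were examined, and tested with camera (limma 3.58.1) with an estimated correlation. The MYB and phenylpropanoid list had no tested member: miR477 and miR530 were detected but filtered out. Shares were compared with two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3.

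The small RNAs named in the text follow a rule set before the data were examined. They passed the threshold, had a mean of at least 5 CPM and did not overlap between the groups, and the largest changes were taken, with at most 2 per family. The difference between leaf types had no overlap condition. Every detected family of a fixed list could be named, up to 4 per list, and not all of these are named. Families outside the lists, apart from the most abundant, were named because they passed the threshold in a comparison, which the rule did not foresee. The test of the difference between leaf types for families, and the searches for siRNAs of the introduced DNA and for bacterial RNA, were added after the data were seen.

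The pipeline was tested on simulated counts with 200 changed small RNAs. The counts were drawn from the dispersions that edgeR had fitted, with 1 mean per small RNA over all groups. They held no listing floor and no difference between groups beyond the changes that were set. False calls that come from the floor or from scaling were therefore not tested. For the infiltrated leaves, over 3631 simulated small RNAs, it made 37 calls with 0 of them false, recovering 2% of the 2-fold and 35% of the 4-fold changes. For the upper leaves it made 44 calls with 1 of them false, recovering 2% and 41%. Over 52 simulated families, 10 of them changed, it made 9 calls with 1 of them false in the infiltrated leaves, recovering 60% of the 2-fold and 100% of the 4-fold changes, and 7 calls with 0 of them false in the upper leaves, recovering 40% and 100%.

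siRNAs were searched for the introduced DNA by translating each in 6 frames. A match was a frame without a stop whose whole translation, at least 5 amino acids, lay within EGFP or the bar herbicide resistance protein. The reversed proteins served as control. The alternatives chosen before the data were examined were the replicate number as a block, DESeq2 1.42.0, RLE factors, total count scaling, other low-count filters, a fold threshold, the compared groups alone, known miRNAs alone, and leaving out each library. Alternatives added after the data were seen were UMI numbers, small RNAs listed in all 12 libraries, unlisted values at 9 reads, scaling to all reads of a library, and merged known miRNAs. Also added then were all reads as the denominator of shares, and leaving out 52 siRNAs. These matched EGFP or bar, or were listed with 1 construct alone in infiltrated leaves, where the source of those without a match is unknown. Nothing in the labels says that libraries came from separate plants, so p-values measure the spread between these samples, which may be technical. Intervals and floors cover counting error only.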

Results

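The series profiled small RNAs in N. benthamiana leaves after transient expression of NlCSP1 or GFP, to look for miRNAs connected with the dwarf growth seen after NlCSP1. Each of the 4 groups, NlCSP1 or GFP in infiltrated or upper leaves, had 3 libraries of 671997 to 1544934 small RNA reads. They listed 249 known miRNAs, 64 predicted miRNAs and 3775 siRNAs. With the reads of all 12 libraries pooled, miR398 (10.1% of small RNA reads), miR159 (8.55%), miR171 (7.48%), miR6149 (5.08%) and miR482 (1.82%) were the most abundant families. The order differed between groups: in GFP upper leaves miR159 and miR171 (116354 ± 8215 and 88873 ± 6540 CPM) lay above miR398 (76799 ± 29392 CPM), which varied most with NlCSP1 in infiltrated leaves (141164 ± 89372 CPM; SD, n = 3). The first principal component, with 57.2% of the variance, separated infiltrated from upper leaves. The second, with 12.7%, separated the constructs in both leaf types. NlCSP1 libraries were at 30.2 to 50.6 in infiltrated and 9.00 to 14.5 in upper leaves. GFP libraries were at -52.7 to -21.0 and at -28.2 to -6.40. On the third, with 8.38%, NlCSP1 infiltrated replicates 2 and 3 lay furthest apart of all libraries, at 52.7 and -42.0.

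The introduced DNA gave a check of the labels. Of the 3775 siRNAs, 26 matched EGFP in translation. All 26 were listed in libraries labelled GFP infiltrated, at 15018 ± 2127 CPM in sum (SD, n = 3), and in no other group. A further 13 matched bar and were listed in both infiltrated groups, at 10495 ± 2205 CPM with NlCSP1 and 7336 ± 1909 CPM with GFP (SD, n = 3), and in no upper library. The reversed proteins gave 0 matches each. The upper leaves held no siRNA that checks their construct label.

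The first comparison asked which small RNAs NlCSP1 changed in the leaves where it was expressed. Some bacterial RNAs also differed between the constructs there, as described below, so effects of the bacteria are not separated from those of NlCSP1. The miR479 family fell from 285 ± 9.46 CPM with GFP to 7.65 ± 1.79 CPM with NlCSP1 (SD, n = 3; log2 fold change -5.16, SE 0.46; edgeR quasi-likelihood, adjusted p = 1.19e-06). miR399, which acts in phosphate homeostasis, fell from 1014 ± 277 to 357 ± 99.3 CPM (log2 -1.51). miR159, a regulator of GAMYB factors, rose from 53628 ± 2966 to 95053 ± 15665 CPM (log2 0.83), and miR6149 from 33132 ± 4088 to 59738 ± 5397 CPM (log2 0.85). miR6019, which targets NLR immune receptor genes, rose from 470 ± 90.4 to 1321 ± 327 CPM (log2 1.49), and miR827, another phosphate-related family, from 635 ± 127 to 1744 ± 656 CPM (log2 1.46).

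In all, 11 of 52 families passed the threshold, 8 higher and 3 lower with NlCSP1. The other higher ones were miR393, miR6024, miR6161 and miR8016 (log2 1.00, 1.22, 1.02 and 0.90), and the other lower one was miR166 (log2 -0.48). Scaling with RLE factors gave 8 higher and 5 lower families, total count scaling 5 and 11, and scaling to all reads 0 and 4, so none of the 8 kept its call there, while miR479 and miR399 kept theirs. The count of 11 became 15 without NlCSP1 replicate 3. It became 5 without GFP replicate 1 and 5 without GFP replicate 2, both of which ended the calls of miR827, miR393, miR6024, miR6161, miR8016 and miR166. Calls also ended for miR6024 and miR8016 without GFP replicate 3, for miR393, miR6161 and miR8016 without NlCSP1 replicate 1 or 3, and for miR166 without NlCSP1 replicate 2.

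Of 31 tested families from the fixed lists 7 passed, and 7 when adjusted over the 31. In the auxin list miR393, which targets auxin receptors, rose, as 1 of 4 families, with 1 adjusted over the list alone. In the leaf and organ development list miR159 rose and miR166, which targets HD-ZIP III factors, fell, of 8 families, with 2 adjusted over the list alone. In the phosphate, sulfate and nitrogen list miR827 rose and miR399 fell, while miR169 (log2 -0.91) and miR395 (log2 1.16) did not pass; 3 of these 4 passed adjusted over the list alone. Without GFP replicate 3 miR395 moved to log2 2.36 and passed. In the NLR list miR6019 and miR6024 rose, of 6 families, with 2 adjusted over the list alone. The copper and oxidative stress families miR397, miR398 and miR408 did not pass (log2 1.08, 1.00 and 0.16, the last turning negative under total scaling and scaling to all reads), and 2 of the 3 passed adjusted over the list alone. miR397 and miR398 fell to log2 0.21 and 0.32 without NlCSP1 replicate 3, and passed without NlCSP1 replicate 2 (log2 1.42 and 1.36). The phase change families miR156, miR157 and miR172 did not pass (log2 0.49, 0.57 and 0.46, the last at -0.067 without NlCSP1 replicate 1), with 0 adjusted over the list alone by edgeR. The silencing families miR162, miR168 and miR403 did not pass either (log2 -0.34, -0.14 and 0.23, the last turning negative under the same scalings), with 0 adjusted over the list alone.

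Of the 7 lists with tested members 0 passed camera with an estimated correlation, and 0 had an unadjusted p below 0.05. The phosphate, sulfate and nitrogen list, where 4 of 16 members fell and 9 passed adjusted over the list alone, shifted downward with an adjusted p = 0.536 with an estimated correlation and 0.0735 with the preset correlation. By fry, which asks whether members moved on balance one way and does not compare them with other small RNAs, its adjusted p was 0.0482. Of single members, 2 of 19 in the auxin list rose, 1 of 57 in leaf and organ development rose and 2 fell, 1 of 10 in silencing fell, 1 of 8 in NLR rose, and 0 of 17 in phase change and 0 of 11 in copper passed. Adjusted over the list alone, 3, 2, 2, 1, 0 and 0 members passed in these 6 lists, in the same order. Phase change and auxin had positive medians (log2 0.48 and 0.13) and an upward camera direction but negative means (-0.0068 and -0.0071).

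Among single small RNAs 214 of 3631 passed, 122 higher and 92 lower, and 879 had an unadjusted p below 0.05. They included 13 known miRNAs, 5 higher and 8 lower. The higher ones were miR6019a, miR167b-3p, miR393a, miR6149a and miR159a_1 (log2 1.49, 1.23, 1.19, 0.85 and 0.83). The named lower ones were miR479a, miR399a_6, miR171i_1, miR399a-5p_3, miR166a, miR169a-5p and miR168-3p (log2 -5.16, -4.29, -3.65, -2.69, -1.38, -1.04 and -0.96). Of the predicted miRNAs, novel_mir95 (Niben101Scf13268, 5611 to 5686) and novel_mir32 (Niben101Scf02246, 231208 to 231314) rose, at log2 2.15 and 1.04. novel_mir73 (Niben101Scf06183, 432754 to 432847) was at 52.0 ± 42.1 CPM with GFP and unlisted with NlCSP1. The siRNAs novel_sir1793, novel_sir1294 and novel_sir3094 were listed only with NlCSP1, at least 275-fold, 120-fold and 82.6-fold above the 10-read listing floor averaged over the GFP group. novel_sir256, novel_sir3459 and novel_sir3031 matched EGFP, were listed only with GFP, and were at least 352-fold, 250-fold and 208-fold above that floor averaged over the NlCSP1 group.

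miR479a, miR171i_1, miR399a-5p_3 and miR166a kept their calls without any 1 library. Without GFP replicate 1 or 2 all 5 higher known miRNAs, miR169a-5p and miR168-3p lost theirs, and without GFP replicate 1 miR399a_6 did too. miR399a_6 moved to log2 -5.23 without NlCSP1 replicate 1. Without NlCSP1 replicate 1 miR167b-3p, miR393a, miR6149a, miR159a_1, miR169a-5p and miR168-3p lost theirs. The calls of miR167b-3p, miR169a-5p and novel_mir73 ended without any 1 of the 6 libraries. Those of miR159a_1 and novel_mir32 ended without any but NlCSP1 replicate 2, that of novel_mir95 without NlCSP1 replicate 3 or any GFP library, and that of miR168-3p without NlCSP1 replicate 3.

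Without 52 siRNAs that matched EGFP or bar, or were listed with 1 construct alone in infiltrated leaves, 149 small RNAs passed, 86 higher and 63 lower. Total count scaling moved the median log2 fold change by -0.25 and gave 80 higher and 242 lower, and scaling to all reads moved it by -0.28 and gave 25 and 89. Of known miRNAs these scalings gave 2 higher and 20 lower, and 0 and 10. The count of 214 became 75 without NlCSP1 replicate 1, and 57, 64 and 349 without GFP replicates 1, 2 and 3; that of 13 known miRNAs became 6 and 20 without NlCSP1 replicates 1 and 2, and 4 and 5 without GFP replicates 1 and 2.

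The second comparison asked what NlCSP1 changed in the upper leaves, which had not been infiltrated. miR391 rose from 168 ± 59.7 CPM with GFP to 4735 ± 1341 CPM with NlCSP1 (SD, n = 3; log2 4.81, SE 0.51; edgeR quasi-likelihood, adjusted p = 8.74e-06). miR479 rose from 14.2 ± 8.69 to 190 ± 13.5 CPM (log2 3.73). miR390, which triggers TAS3 siRNAs against auxin response factors, rose from 260.0 ± 23.6 to 666 ± 181 CPM (log2 1.36), and miR3627 from 1.27 ± 0.566 to 10.2 ± 3.53 CPM (log2 2.91). miR159 fell from 116354 ± 8215 to 78025 ± 5299 CPM (log2 -0.58) and miR827 from 1961 ± 285 to 739 ± 364 CPM (log2 -1.41). In GFP upper replicate 1 the member miR159a_1 held 144538 of the 144541 reads of miR159. Tested as a single small RNA, miR159a_1 did not pass in upper leaves.

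In all, 17 of 52 families passed, 7 higher and 10 lower. Of the 31 fixed-list families 11 passed, and 12 when adjusted over the 31. In the NLR list miR6019 and miR6020 rose (log2 1.22 and 1.39), and miR6021 and miR482 fell (log2 -1.61 and -0.78), of 6 families; 5 passed adjusted over the list alone. In the auxin list miR390 and miR393 rose (log2 1.36 and 0.89), miR160, which targets auxin response factors, fell (log2 -0.79), and miR167 did not pass (log2 0.37); 3 of these 4 passed adjusted over the list alone. In the silencing list miR162, which targets DCL1, and miR403, which targets AGO2, fell (log2 -1.26 and -0.54), and miR168, which targets AGO1, did not pass (log2 -0.41), with 2 adjusted over the list alone. In the leaf and organ development list miR159 fell, as 1 of 8 families, and in the phosphate, sulfate and nitrogen list miR827 fell, as 1 of 4, with 1 adjusted over the list alone in either. The phase change families miR156, miR157 and miR172 did not pass (log2 0.26, -0.35 and -0.19, the last turning positive under total scaling and scaling to all reads, the first at -0.10 without GFP replicate 3). The copper families miR397, miR398 and miR408 did not pass either (log2 0.94, 0.43 and 0.13), and 0 did adjusted over either list alone by edgeR. Outside the lists miR5368, miR4995 and miR6155 fell (log2 -2.18, -2.40 and -1.17). Total scaling gave 8 higher and 6 lower families, and scaling to all reads 7 and 4, ending the calls of miR159, miR162, miR482, miR6155, miR160 and miR403. The call of miR160 also ended without any 1 of the 6 upper libraries, and that of miR403 without any but NlCSP1 replicate 3. Calls ended for miR4995 without any NlCSP1 library or GFP replicate 2, and for miR393 without NlCSP1 replicate 1 or 2 or GFP replicate 3. Total scaling ended the calls of miR159, miR160, miR403 and miR4995.

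Of the 7 lists 0 passed camera with an estimated correlation, and 1, the auxin list, had an unadjusted p below 0.05. That list shifted upward with an adjusted p = 0.226 with an estimated correlation and 0.0209 with the preset correlation. By fry, without comparison to other small RNAs, its adjusted p was 0.00134. Of its 19 members 5 rose and 0 fell, and 8 passed adjusted over the list alone. In the leaf and organ development list 4 of 57 members rose and 1 fell, with 8 adjusted over the list alone, and its median (log2 -0.38) and camera direction were downward while its mean was positive (0.037). In the NLR list 2 of 8 rose and 1 fell, with 6 adjusted over the list alone, and in the phosphate, sulfate and nitrogen list 1 of 16 fell, with 1. In the phase change, copper and silencing lists 0 members passed, and 0, 1 and 0 did adjusted over the list alone by edgeR. Phase change had a mean of 0.066 and an upward direction by fry but a downward one by camera.

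Among single small RNAs 138 of 3631 passed, 63 higher and 75 lower, and 634 had an unadjusted p below 0.05. Of 21 known miRNAs, 16 were higher and 5 lower. The named higher ones were miR391-3p_2, miR391, miR479a, miR166m_2, miR3627-3p_2, miR166-3p, miR171i_1 and miR390a-5p (log2 7.12, 4.84, 3.73, 3.66, 2.91, 2.53, 2.42 and 1.83). The lower ones were miR5368, miR827-5p_3, miR6021, miR171d_1 and miR6155 (log2 -2.18, -1.88, -1.61, -1.35 and -1.17). The predicted miRNA novel_mir13 (Niben101Scf00675, 406281 to 406347) rose from 579 ± 115 to 2720.0 ± 983 CPM, and novel_mir64 (Niben101Scf05396, 315355 to 315629) fell from 336 ± 109 to 60.5 ± 13.8 CPM. The siRNAs novel_sir6980, novel_sir9204 and novel_sir6705 were listed only with NlCSP1 among the upper leaves, the first at 45.7 ± 9.18 CPM. novel_sir8451, novel_sir9120 and novel_sir6121 were listed there only with GFP, the first at 75.3 ± 13.9 CPM. With unlisted values set to 9 reads the calls of novel_sir6705 and novel_sir6121 ended.

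miR391-3p_2, miR391, miR479a, miR166-3p, miR171i_1, miR6021 and novel_mir13 kept their calls without any 1 library. All other named known miRNAs lost theirs without NlCSP1 replicate 1. Calls also ended without NlCSP1 replicate 2 for miR390a-5p, miR827-5p_3 and miR6155, and without NlCSP1 replicate 3 for miR166m_2 and miR6155. Without GFP replicate 1 this held for miR3627-3p_2 and miR390a-5p, without GFP replicate 2 for miR166m_2, miR3627-3p_2, miR5368 and miR6155, and without GFP replicate 3 for miR166m_2, miR3627-3p_2, miR390a-5p and miR6155. miR166m_2 moved to log2 2.88 without NlCSP1 replicate 1 and 5.99 without GFP replicate 1. The call of novel_mir64 ended without any 1 of the 6 libraries, that of novel_sir8451 without any but NlCSP1 replicate 3, and that of novel_sir6121 without NlCSP1 replicate 1 or 2.

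Total count scaling moved the median log2 fold change in upper leaves by 0.24 and gave 87 higher and 36 lower, and scaling to all reads moved it by 0.37 and gave 36 and 10. The count of 138 became 56, 66 and 157 without NlCSP1 replicates 1, 2 and 3, and 79 and 82 without GFP replicates 2 and 3. That of 21 known miRNAs became 9 without NlCSP1 replicate 1, and 12 and 12 without GFP replicates 2 and 3.

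The third comparison tested whether the NlCSP1 effect differed between the leaf types. miR479 had opposite effects, at log2 -5.16 in infiltrated and 3.73 in upper leaves, a difference of -8.89 (SE 0.63; edgeR quasi-likelihood, adjusted p = 5.09e-08). miR827 went the other way, 1.46 against -1.41, a difference of 2.87. miR391 was at 0.77 and 4.81, a difference of -4.05, but the former was -0.065 without NlCSP1 infiltrated replicate 3 (difference -4.93), and miR3627 at -0.67 and 2.91, a difference of -3.57. miR399 differed by -1.98 and miR390 by -1.48. The difference of miR390 no longer passed without GFP infiltrated replicate 1 or 2 or NlCSP1 upper replicate 1, or with known miRNAs alone.

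In all, 10 of 52 families differed, 5 in each direction, and the 6 above kept this under total scaling (3 and 9 families) and scaling to all reads (1 and 5). miR159 and miR6149 (differences 1.40 and 1.23) lost it under scaling to all reads, where the upper-leaf value of miR6149 also turned from -0.38 to 0.012. miR6155 and miR6021 (1.36 and 1.16) lost it under both, miR6021 also without any 1 library other than NlCSP1 infiltrated replicates 1 and 2, and the infiltrated-leaf value of miR6155 turned from 0.19 to -0.11 and -0.26, and to -0.069 without GFP infiltrated replicate 3. Of 3631 small RNAs 68 differed, 25 with the higher effect in infiltrated leaves and 43 with the lower, and 633 had an unadjusted p below 0.05. The known miRNAs miR827-5p_3 and miR159a_1 (log2 3.11 and 1.40) and miR479a, miR391-3p_2, miR171i_1, miR391-5p and miR3627-3p_2 (log2 -8.90, -6.64, -6.07, -4.06 and -3.58) were among them. Without NlCSP1 infiltrated replicate 3 miR391-3p_2 and miR391-5p were at -7.37 and -4.97. The call of miR159a_1 ended without any 1 library other than NlCSP1 infiltrated replicates 2 and 3 and GFP infiltrated replicate 3. That of miR3627-3p_2 ended without NlCSP1 infiltrated replicate 1 or 2, NlCSP1 upper replicate 1, GFP infiltrated replicate 1 or 2, or any GFP upper library. Total scaling moved the median by -0.54 and gave 19 and 134, and scaling to all reads moved it by -0.71 and gave 6 and 50. The count of 68 became 29 and 183 without NlCSP1 infiltrated replicates 1 and 3, 36 without NlCSP1 upper replicate 2, 35, 34 and 159 without GFP infiltrated replicates 1, 2 and 3, and 37 without GFP upper replicate 3.

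Across the 3631 small RNAs, which are not independent replicates, the effects in both leaf types had a Spearman rho of 0.233 and a Pearson r of 0.104. Of the calls, 9 were higher in both and 8 lower in both, where independent lists would share 2.12 and 1.90. Another 3 were lower in infiltrated and higher in upper leaves, with 1.60 from independent lists, and 0 the reverse.

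**Figure D1:**
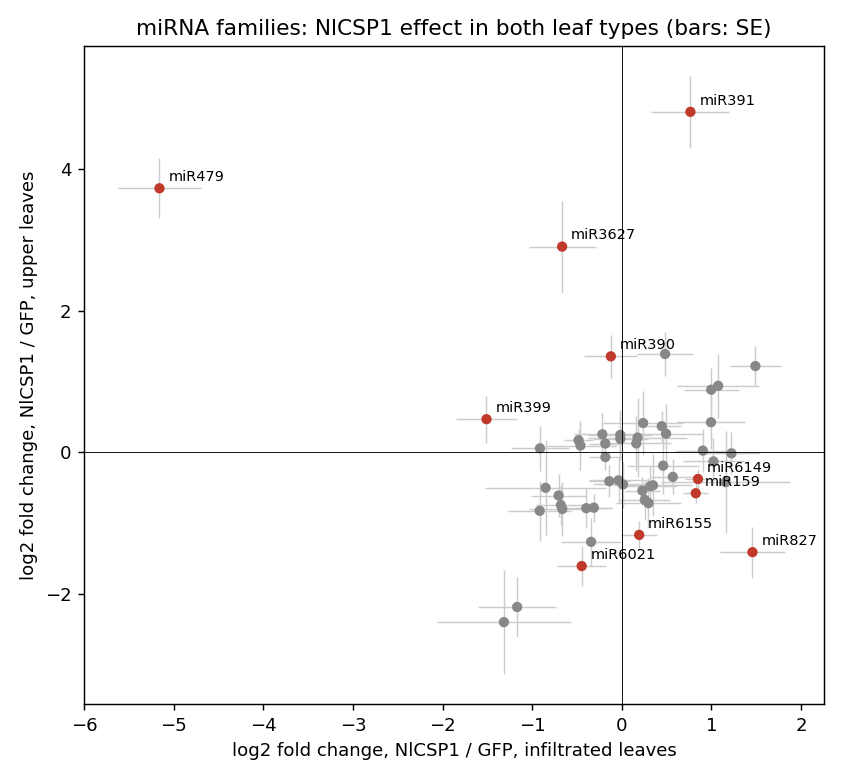
Each point is 1 of 52 miRNA families, with the NlCSP1 against GFP log2 fold change in infiltrated leaves on the x axis and in upper leaves on the y axis, bars showing the standard error. The 10 families whose effect differed between leaf types are red and named; miR479 lies at -5.16 and 3.73, and the upper-leaf sign of miR6149 and the infiltrated-leaf sign of miR6155 turn under other scalings.

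**Figure D2:**
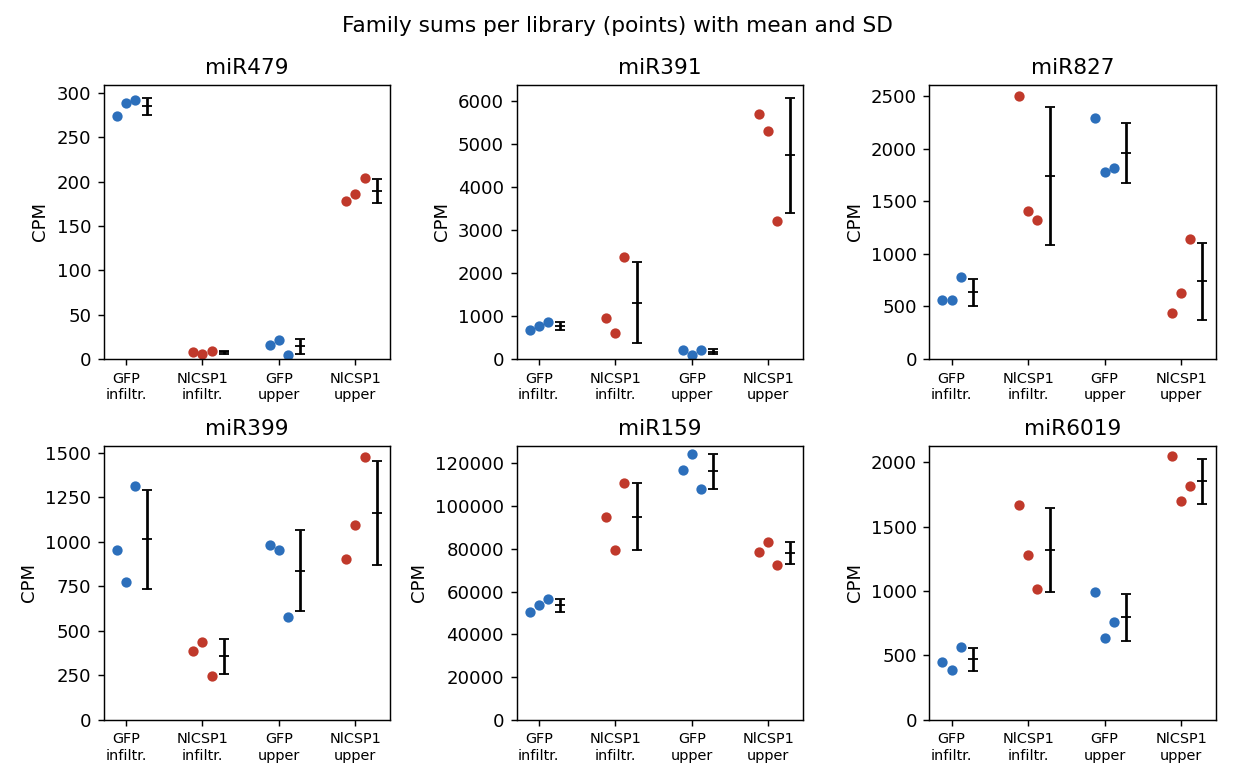
CPM of 6 families in each of the 12 libraries (points), with the group mean and SD beside them and axes that start at 0. miR479 averaged 285 CPM in GFP infiltrated leaves and 7.65 CPM in NlCSP1 infiltrated leaves, with 14.2 CPM in GFP and 190 CPM in NlCSP1 upper leaves.

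The fourth comparison set infiltrated against upper leaves within each construct. With GFP, miR479 was higher in infiltrated leaves (log2 4.32, SE 0.43; edgeR quasi-likelihood, adjusted p = 2.17e-06), as were miR3627 (6.98), miR391 (2.19), miR390 (2.17) and miR6157 (2.25). The GFP upper libraries held 1, 1 and 2 reads of miR3627. Its value here, its upper-leaf effect and its difference between leaf types rest on these few reads. miR164, which targets NAC factors, and miR396, which targets growth-regulating factors, were lower (log2 -1.78 and -1.11). With NlCSP1, miR3627 and miR6157 were higher too (3.41 and 2.16) and miR164 and miR396 lower (-1.65 and -1.23), but miR479 and miR391 were lower (-4.57 and -1.85). Of 52 families 35 passed with GFP, 6 higher and 29 lower, and 21 with NlCSP1, 5 higher and 16 lower (edgeR quasi-likelihood). With GFP, total scaling gave 6 higher and 15 lower families and scaling to all reads 7 and 0, so that miR164 and miR396 did not pass there (log2 -1.05 and -0.42). With NlCSP1 these scalings gave 3 and 19, and 3 and 13.

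With GFP 2005 small RNAs passed, 1086 higher and 919 lower in infiltrated leaves, and with NlCSP1 1485, 889 higher and 596 lower. Scaling to all reads moved the GFP median by 0.65 and gave 1225 higher and 267 lower, and total scaling gave 793 and 803 with NlCSP1. Among known miRNAs with GFP, miR156i-3p_1, miR3627-3p_2, miR319f_1, miR391-3p_2 and miR479a were higher, and miR160a-5p, miR6161a, miR164b, miR164a_4 and miR4995 lower. With NlCSP1, miR156z, miR156i-3p_1, miR319f_1, miR3627-3p_2 and miR171b-3p_2 were higher, and miR479a, miR171i_1, miR171e-5p, miR399a_6 and miR164b lower. With GFP the call of miR4995 ended without any 1 of the 6 libraries, and that of miR164b without GFP infiltrated replicate 2 or 3 or GFP upper replicate 2. With NlCSP1 that of miR399a_6 ended without NlCSP1 infiltrated replicate 2 or NlCSP1 upper replicate 3. miR319f_1 was at 1552 ± 226 CPM in infiltrated and 41.0 ± 18.2 CPM in upper leaves with NlCSP1 (SD, n = 3).

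siRNAs of 22 nt and 24 nt moved apart with leaf position. With GFP 523 of 932 siRNAs of 22 nt were higher in infiltrated leaves and 30 lower, while 254 of 1752 siRNAs of 24 nt were higher and 723 lower. With NlCSP1 the numbers were 390 and 39 at 22 nt, and 220 and 434 at 24 nt. Scaling to all reads turned the direction of the 24-nt calls with GFP, to 297 higher and 224 lower, and gave 163 and 259 with NlCSP1, while the 22-nt calls were 578 and 8 with GFP and 313 and 24 with NlCSP1.

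The last comparison was of small RNA classes and lengths. Known miRNAs took 39.5 ± 8.61% of small RNA reads with NlCSP1 and 34.7 ± 1.49% with GFP in infiltrated leaves (SD, n = 3; exact permutation p = 0.5), and 48.9 ± 1.35% and 46.0 ± 6.06% in upper leaves (exact permutation p = 0.5). The difference of 4.88 percentage points in infiltrated leaves was 0.335 without NlCSP1 replicate 3 and 8.89 without NlCSP1 replicate 2. That of 2.83 in upper leaves was 0.221 without GFP replicate 3 and 6.15 without GFP replicate 1. Small RNAs of 24 nt took 16.4 ± 0.794% against 18.0 ± 0.470% in infiltrated leaves and 23.3 ± 0.850% against 19.8 ± 1.41% in upper leaves. Those of 22 nt took 18.7 ± 1.15% against 23.9 ± 1.62% in infiltrated leaves. Each of these 3 differences had no overlap and the smallest p that 3 against 3 allows (exact permutation p = 0.1, adjusted 0.218 over 24 tests). As shares of all reads the 24-nt differences had exact permutation p = 0.5 and 0.2, and as shares of distinct small RNAs they turned, to 2.02 and -0.380 percentage points. Other classes also varied. rRNA took 5.39 ± 3.17% of all reads with NlCSP1, from 2.04% to 8.34%, and 2.80 ± 0.266% with GFP in infiltrated leaves. Exon sequence took 1.80 ± 0.209% with NlCSP1 and 4.20 ± 2.30% with GFP in upper leaves, without overlap.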

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

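The test of the difference for small RNAs and total scaling were planned. The test of the difference for families, scaling to all reads, the search for bacterial RNA and what each test of an explanation would show, the counts over other splits of the samples included, were set down after the results had been seen.

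The NlCSP1 effect differed between infiltrated and upper leaves for 68 small RNAs by a test of the difference itself. Among the 12 known miRNAs that differed were miR827-5p_3 (log2 3.11), miR159a_1 (1.40), miR479a (-8.90), miR391-3p_2 (-6.64), miR171i_1 (-6.07), miR391-5p (-4.06) and miR3627-3p_2 (-3.58). The families were miR159 (1.40), miR3627 (-3.57), miR390 (-1.48), miR391 (-4.05), miR399 (-1.98), miR479 (-8.89), miR6021 (1.16), miR6149 (1.23), miR6155 (1.36) and miR827 (2.87).

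Exchanged leaf labels could give such a difference, but reads of Agrobacterium sRNAs matched the leaf label in 12 of 12 libraries. Scaling as the whole cause is argued against for miR3627, miR391, miR399, miR479 and miR827, which kept sign and call under TMM, total scaling and scaling to all reads. miR3627 rests on 1, 1 and 2 reads in the GFP upper libraries. miR390 kept sign and call under these scalings too, but its call ended with known miRNAs alone, which also rescales the libraries. For miR159, miR6021, miR6149 and miR6155 scaling cannot be told apart from an effect of NlCSP1, since their differences under scaling to all reads were 0.842 to 1.43 standard errors. Exchanged construct labels in the upper leaves also stay open, because 0 siRNAs matching EGFP were listed there. With exchanged labels the 9 and 8 calls shared in direction would be opposite and the 3 opposite ones shared. The second principal component, which placed the constructs alike in both leaf types, would then place them oppositely. A systemic response to NlCSP1 that differs from the local one remains a hypothesis beside exchanged labels. So does the bacterial difference between constructs in infiltrated leaves, given below.

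Of 100 splits of the samples, a random draw from a larger number, 1 gave as many as 68 small RNAs, the real one. The highest other gave 67; it reversed the construct of all upper libraries and exchanged 1 infiltrated library of each construct. With 67 against 68 calls, and only part of the splits drawn, these counts do not exclude chance. The split that reverses the construct of all upper libraries and nothing else was not drawn, so these counts leave exchanged upper labels open as well.

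Reads outside the main measurement carried a bacterial signal. Agrobacterium sRNAs reached 27.2 ± 17.2 RPM with NlCSP1 and 17.9 ± 7.61 with GFP in infiltrated leaves (SD, n = 3), and 0 reads in the 6 upper libraries, which allows up to 0.139 RPM in the shallowest. Bacterial RNase P RNA was at 14.4 ± 5.89 and 2.84 ± 0.887 RPM, and the tmRNA of cyanobacterial type at 331 ± 257 and 37.8 ± 13.7. The tmRNA of alphaproteobacteria was at 32.5 ± 3.97 and 18.1 ± 6.20, and the sRNA ar35 at 15.8 ± 10.2 and 6.18 ± 1.53. The CRISPR direct repeat went the other way without overlap, at 1.02 ± 0.358 with NlCSP1 and 5.09 ± 1.01 with GFP, and ctRNA was at 12.3 ± 4.78 and 15.8 ± 2.59. Upper leaves were not free of such reads: there the tmRNA of alphaproteobacteria was at 4.00 ± 2.93 RPM with NlCSP1 and 5.10 ± 1.82 with GFP, and that of cyanobacterial type at 0.938 ± 0.139 and 1.19 ± 0.631. Among infiltrated libraries NlCSP1 replicate 2 was highest for Agrobacterium sRNAs and for tmRNA of cyanobacterial type, at 46.5 and 618 RPM. NlCSP1 replicates 1 and 3 were at 21.8 and 13.4 RPM for the former, and at 251 and 123 for the latter.

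RNase P RNA was 5.08-fold higher with NlCSP1 (exact permutation p = 0.1, the smallest possible). More Agrobacterium cells in all NlCSP1 samples could raise it, but RNase P reads per Agrobacterium sRNA read were 3.43-fold higher too, without overlap. Libraries rich in structural RNA could raise it as well, but RNase P reads per rRNA read were 2.90-fold higher, again without overlap. Another bacterium, or a bacterial response to the construct, stays open and was not tested. In infiltrated leaves RNase P RNA, the tmRNAs and the CRISPR repeat differed between constructs without overlap, while Agrobacterium sRNAs, ar35 and ctRNA overlapped. Small RNA changes with NlCSP1 there cannot be told apart from effects of this bacterial difference. The same holds for the differences between leaf types.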

How the results depend on the processing

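UMI numbers, small RNAs listed in all 12 libraries, unlisted values at 9 reads, scaling to all reads, merging and the all-reads denominator were chosen after seeing the data. So was leaving out siRNAs that matched EGFP or bar, or were listed with 1 construct alone in infiltrated leaves. Libraries with the same replicate number were no more alike than others (median correlation -0.02 against 0.02). Of 12 libraries 3 were closest to their own number. With 3 libraries per group this cannot exclude shared plants or batches. With the replicate block, the counts in infiltrated leaves, upper leaves and their difference were 78, 71 and 21, and 6 known miRNAs passed in infiltrated leaves. In the same order DESeq2 gave 592, 393 and 321, with 37 and 39 known miRNAs and 19 families in infiltrated leaves. Total scaling gave 322 in infiltrated leaves (22 known miRNAs) and 153 for the difference. The compared groups alone gave 53 and 5 known miRNAs in infiltrated leaves. Known miRNAs alone, with fewer tested, gave 21, 27 and 22, 40 and 36 between leaf types, and a rho of 0.203. Over all 3631 small RNAs Pearson r was 0.104. Small RNAs in all 12 libraries gave 28 known miRNAs in infiltrated leaves and 220 small RNAs in upper leaves. Unlisted values at 9 reads gave 485, 274 and 115, and 26 known miRNAs in infiltrated leaves. Scaling to all reads gave 114 and 46 small RNAs, 4 and 11 families, and 12 known miRNAs in upper leaves. In infiltrated leaves fry called 1 list, and in upper leaves fry and the preset correlation 1 each. Except where stated, the cause was not tested.

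Leaving out 1 library gave 57 to 349, 56 to 157 and 29 to 183 small RNAs, 4 to 20 and 9 to 21 known miRNAs, 5 to 15 and 13 to 16 families in infiltrated and upper leaves, 1602 to 1798 and 1184 to 1690 between leaf types, and a rho of 0.174 to 0.263. How these counts split into higher and lower calls is not given here, and the balance of directions may depend on single libraries. The share of known miRNAs differed by 0.335 to 8.89 and 0.221 to 6.15 percentage points in infiltrated and upper leaves. With distinct small RNAs in place of counts, the difference reversed for known miRNAs in upper leaves (-0.482 percentage points) and for 24 nt in infiltrated (2.02) and upper leaves (-0.380).

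Of 38 called family effects, 557 alternatives kept the call, 99 lost it and 0 reversed; of 69 called small RNA effects, 1053 kept it, 187 lost it and 0 reversed. Uncalled families changed sign in infiltrated leaves: miR168 and miR390 with known miRNAs alone (0.10 and 0.12), and miR403 (-0.081, -0.18) and miR408 (-0.17, -0.089) with total scaling and all reads. Leaving out 1 library also did so there for miR168 (-0.33 to 0.010), miR172 (-0.067 to 0.74) and miR408 (-0.34 to 0.40). In upper leaves miR172 changed sign with total scaling (0.028) and all reads (0.14), and leaving out 1 library did so for miR156 (-0.10 to 0.82), miR169 (-0.13 to 0.30), miR172 (-0.36 to 0.21), miR395 (-0.88 to 0.16) and miR408 (-0.12 to 0.54). At this depth, spread and number of libraries, simulated 2-fold changes were recovered in 2% of small RNAs; the part of depth alone was not tested.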

Other observations

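The calls and fold changes of the main test and total scaling were planned. The sums of siRNAs confined to 1 leaf type, their counts by length, the match to bar, the pairing of strands and scaling to all reads were chosen after the results had been seen, and what the counts over other splits of the samples would show was written down afterwards too.

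siRNAs listed in 1 leaf type alone differed in length. The 119 siRNAs listed in all 6 infiltrated and no upper library summed to 48309 ± 10584 CPM (SD, n = 6); 54 of them had 18 to 20 nt, 49 had 21 or 22 nt and 12 had 24 nt. The 34 siRNAs listed in all 6 upper and no infiltrated library summed to 785 ± 94.4 CPM, and 31 of them had 24 nt. In infiltrated leaves 78 of 1752 siRNAs of 24 nt were higher and 24 lower with NlCSP1, which turned to 58 and 69 under total scaling and 18 and 23 under scaling to all reads. At 22 nt 12 of 932 were higher and 24 lower, against 3 and 83 under total scaling and 0 and 23 under scaling to all reads.

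A candidate source of the siRNAs confined to infiltrated leaves is the introduced DNA. Of the 119, 12 matched the bar protein and the reversed protein matched 0, which fits that source for those 12. The other 107 matched neither protein; without the plasmid sequence their source cannot be told apart from the plant genome.

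miR479a and miR171i_1 had the same order of groups, lower with NlCSP1 in infiltrated leaves (log2 -5.16 and -3.65) and higher in upper leaves (log2 3.73 and 2.42). They may be both strands of one duplex: miR479a paired with miR171i_1 at 18 positions, the most of 166 known miRNAs, where the median was 8 and the highest outside the miR170 and miR171 families was 11.

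In each comparison of 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. In infiltrated leaves the real split gave 214 small RNAs, 13 known miRNAs and 11 families, and the highest other split 16, 1 and 0. In upper leaves the values were 138, 21 and 17, and the highest other 12, 0 and 0. Infiltrated against upper leaves gave 2005 with GFP (highest other 9) and 1485 with NlCSP1 (highest other 0). In each of these the real split was the only 1 of 10 with a count as large. For fixed lists all 10 splits gave 0 in either leaf type.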
